A study of Mus musculus with 8 samples.

How the data were processed

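Gene expression was measured on 8 Agilent 1-colour arrays, 4 of knockout (KO) and 4 of wild-type (WT) placenta, with the group of each sample taken from its genotype label. Per the labels, total RNA was amplified into cRNA carrying Cy3. The deposited intensity values were read from the scanned images with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes. Per the file headers, the processed intensity is the spot's brightness after subtraction of a spatially fitted background and a further detrending, with surrogate values for dim spots and no scaling between arrays, and probe positions are on mm9 (NCBI37). The flags for spots well above background, outlier spots and saturated spots were used as the authors deposited them. The authors' deposited table of intensity values served as an alternative: its column medians were 59.8, 59.5, 59.5 and 59.7 for KO 1 to KO 4 and 59.7, 59.6, 59.7 and 59.7 for WT 1 to WT 4, and each column kept the order of that array's processed signal (Spearman rho of 1.00). Its scale is linear and its direction that of brightness, and how the columns were brought to a common distribution is not given in the sources used here.

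Of 59305 spots other than controls, those marked as outliers were left out, spots of a probe were averaged, and 55681 probes remained. The log2 processed signal minus the array's 75th percentile was the value used throughout. Probe names came from the accession of each probe through a RefSeq gene table (assembly GRCm38.p6, used for names only), which matched 26582 probes, and 29099 probes kept the name in the files. Probes well above background on at least 4 of 8 arrays, with at least 3 values in each group, were kept, and a gene was represented by its probe with the highest mean, giving 17532 genes, of which 5160 have only an accession or clone name. Several probes passed for 3814 genes, and the text gives the other probe where it differed. No column of values was left unused.

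KO and WT were compared with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p below 0.05) in 1 fit of the 8 arrays without covariates. Shifts of 23 gene lists were tested with limma's camera (preset correlation of 0.01, adjusted over the 23 lists), which compares a list with all other genes, and with an estimated correlation and limma's fry as alternatives. fry tests whether the members of a list move one way on balance, and its mixed test, which asks for change in either direction, called 1 list, the hypoxia response (adjusted p = 0.0049). The lists hold 609 measured genes, 21 of them in more than 1 list, and cover the imprinted region, other imprinted genes, endothelium, angiogenic signals, 4 kinds of trophoblast, nutrient transport, decidua, natural killer and T cells, macrophages, erythroid cells, yolk sac, mesenchyme, matrix, hypoxia, inflammation, phagocytosis, cell cycle, apoptosis, stress and sex-linked genes. Measures of array quality were compared with exact two-sided permutation tests of the group means.

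The genes named were chosen by a rule. It names Rtl1 and every measured member of the Dlk1-Dio3 list. It names up to 12 genes per direction of largest change among those past the threshold whose groups do not overlap or, where fewer than 5 pass, the 5 of smallest p whose groups do not overlap, stated as not passing. It also names the 3 members of smallest p in each list. Genes known only by an accession or clone name were counted and not named. Genes outside this rule, such as Prl3b1, Gzme, Gzmf and 6430411K18Rik, were picked after their values were seen.

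The tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were normexp background correction (offset of 50), quantile normalization, scaling on the median of detected probes, the authors' values, no filter or a filter on all 8 arrays, the mean of a gene's probes, eBayes with trend and robust options, array weights, slide column as a replicate block, the decidua list as a covariate, a further threshold of 1.5-fold, lists without shared genes and leaving out each array. The yolk sac list as a covariate, the exact permutation of list means per array, the comparison of outlier spot counts and a list of uterine epithelium genes were added after the data were seen.

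The procedure was tested on simulated data for KO against WT with 16945 genes. Of 50 genes changed at each size, 8% were recovered at 1.5-fold, 66% at 2-fold, 90% at 3-fold and 96% at 4-fold, with 4 false calls. The genes of all sizes were changed in the same run, which eases the adjusted threshold. These shares therefore overstate recovery where few genes change. Of 22 unchanged lists 0 were called by camera, and a list shifted by -0.3 was called. The simulated genes were drawn independently, so this does not test camera on lists whose members move together. The estimated correlation was 0.51 in the natural killer and T cell list and 0.61 in the yolk sac list. Software versions were R 4.3.3, limma 3.58.1, statmod 1.5.0 and the data.table package, version 1.17.8. Per the file headers, the median coefficient of variation of repeated probes was 10.2% to 17.5% and the SD of negative controls 11.9 to 35.5, which limits the precision of dim probes.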

Results

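Placental RNA from mice labelled as knockout for Rtl1 (also called Peg11) was compared with RNA from wild-type mice at embryonic day 10.5. Rtl1 is a retrotransposon-derived imprinted gene of the Dlk1-Dio3 region, expressed from the paternal allele. The series asks which genes help to keep the endothelium of the fetal capillaries intact at this early stage of the placenta. Each of 8 samples, 4 knockout (KO) and 4 wild-type (WT), was labelled with Cy3 and hybridised to its own 1-colour oligonucleotide array. The labels give all embryos as male and of the C57BL/6J strain. They name the placenta as the tissue, whereas the RNA extraction notes name the embryo. The lactogen gene Prl3b1, a product of trophoblast, was well above background on all 8 arrays, at 7.74 ± 0.20 log2 units above the 75th percentile of the array in KO and 7.83 ± 0.37 in WT (SD, n = 4 each). The labels do not say whether the samples of a group came from separate animals or litters, so p-values measure only the spread between these samples. The number of arrays limits the precision of every value.

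The targeted gene gave no firm check of the labels. Rtl1 was represented by 1 probe, at 110828379 to 110828438 of chromosome 12 (mm9), which was not well above background on any of the 8 arrays, so no fold change is given. Its signal lay between -5.51 and -4.50 on the KO arrays and between -4.77 and -3.41 on the WT arrays. On the KO arrays it lay near the Kdm5d probe (-5.70 to -4.62), also not well above background. On WT 2, WT 3 and WT 4 it lay at -3.75, -4.36 and -3.41, above Kdm5d at -5.87, -6.19 and -4.99. On WT 1 it lay at -4.77, against -4.85 for Kdm5d. Signals this dim do not settle the labels, since a Uty probe not well above background on WT 3 lay at -4.44 there. Which part of Rtl1 was deleted, and through which parent the knockout allele was passed on, is not given in the sources used here. The Y-linked genes Ddx3y, an RNA helicase, and Eif2s3y, a translation factor subunit, were well above background on all 8 arrays, with log2 values from 1.21 to 1.84 and from 0.67 to 1.67. Xist, the RNA that coats the inactive X chromosome of female cells, was read by 2 probes that were below that level on every array, and so gave no measure of maternal tissue. Kdm5d was likewise not well above background on any array, and each of the 2 Uty probes was so on 1 of 8.

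Brightness and background did not separate the groups. The 75th percentile of the processed signal ranged from 629 to 1490 over the 8 arrays (exact two-sided permutation test, p = 0.857), and no spot was saturated. The mean local background was 48.6 ± 3.42 in KO and 46.7 ± 2.65 in WT (SD, n = 4 each, exact p = 0.429), and the share of spots well above background was 42.2% ± 3.04 and 43.7% ± 4.12 (exact p = 0.571). Spots marked as outliers by the scanner software numbered 1527 ± 562 on KO arrays and 718 ± 235 on WT arrays, without overlap of the groups. The exact p of this comparison, made after the counts were seen, was 0.0286, the smallest that 4 against 4 can give, and 0.114 after adjustment over 4 measures. All 8 arrays lay on 1 slide with 1 scan time, KO in row 1 and WT in row 2, so slide row and genotype cannot be told apart. Correlations between arrays had a median of 0.978 within groups (12 pairs) and of 0.978 between groups (16 pairs), across 16945 genes, which are not independent replicates.

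Meox2 fell in KO placentas. Meox2, a homeobox transcription factor of mesoderm and vascular cells, was 2.73-fold lower, at a log2 signal of -0.22 ± 0.19 in KO against 1.22 ± 0.14 in WT (SD, n = 4 each), and all 4 KO arrays lay below all 4 WT arrays (limma, log2 fold change -1.45 ± 0.13 SE, adjusted p = 0.0418). Its 1 probe lies at 37905809 to 37905868 of chromosome 12 (mm9) and was well above background on all 8 arrays. Of 17532 genes tested, limma called 0 higher and 1 lower in KO. At an unadjusted p below 0.05 it gave 101 genes higher and 1028 lower, 1129 in all against 877 expected by chance. With median scaling it gave 215 higher and 484 lower, fewer in all than expected by chance. Other settings called 0 genes higher and 0 to 2 lower, except that array weights gave 3 higher and 50 lower. Meox2 kept its call without KO 4 (limma adjusted p = 0.0479) but lost it without KO 1 (0.098), KO 2 (0.183), KO 3 (0.162), WT 1 (0.0516), WT 2 (0.338), WT 3 (0.185) or WT 4 (0.265), with a log2 fold change from -1.54 to -1.40. It also lost its call with normexp background correction (0.0678), median scaling (0.141), no filter on dim probes (0.674), slide column as a block (0.133) and the decidua list as a covariate (0.0811).

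The next genes lower in KO did not pass the threshold. Tmem100, an endothelial membrane protein, had a log2 fold change of -1.74 ± 0.23 (SE, limma adjusted p = 0.162). Pcdh19, an X-linked protocadherin, had -1.12 ± 0.13 (limma adjusted p = 0.0955). Cat, which encodes catalase, had -1.20 ± 0.15 (limma adjusted p = 0.113), while its other probe gave -0.27. Pde4b, a cyclic AMP phosphodiesterase, had -1.62 ± 0.21 (limma adjusted p = 0.189) on a probe well above background on 1 KO and 3 WT arrays, so signals near background enter this value, which was -0.95 with normexp. With array weights all 4 passed, at limma adjusted p values of 0.00762 for Tmem100, Pcdh19 and Cat and 0.027 for Pde4b. That fit weighted WT 3 at 4.58 and KO 3 at 2.29, against 0.38 to 1.56 for the other arrays, so it rests largely on WT 3 and KO 3. The same limit holds for every other result with array weights.

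Genes higher in KO did not pass either, and the 5 of smallest p among those whose groups did not overlap were Pomgnt2, Prr9, Ckap5, Cd34 and Crct1. Pomgnt2, a glycosyltransferase acting on dystroglycan, was at 2.45 ± 0.41 in KO (SD, n = 3) and 1.33 ± 0.22 in WT (SD, n = 4; limma adjusted p = 0.409), and passed with array weights (log2 fold change 1.40, limma adjusted p = 0.0483). Prr9 and Crct1, members of a cluster of skin barrier genes on chromosome 3, had log2 fold changes of 1.63 ± 0.37 and 1.68 ± 0.42 (SE). Ckap5, a microtubule-binding protein of the spindle, had 0.58 ± 0.14. Cd34, a surface glycoprotein of endothelium and blood progenitors, had 0.61 ± 0.15, while its dimmer probe gave 0.02. Over all genes, groups did not overlap for 50 genes higher and 715 lower in KO, or 4.36% of the genes tested, where chance gives 2.86%.

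**Figure D1:**
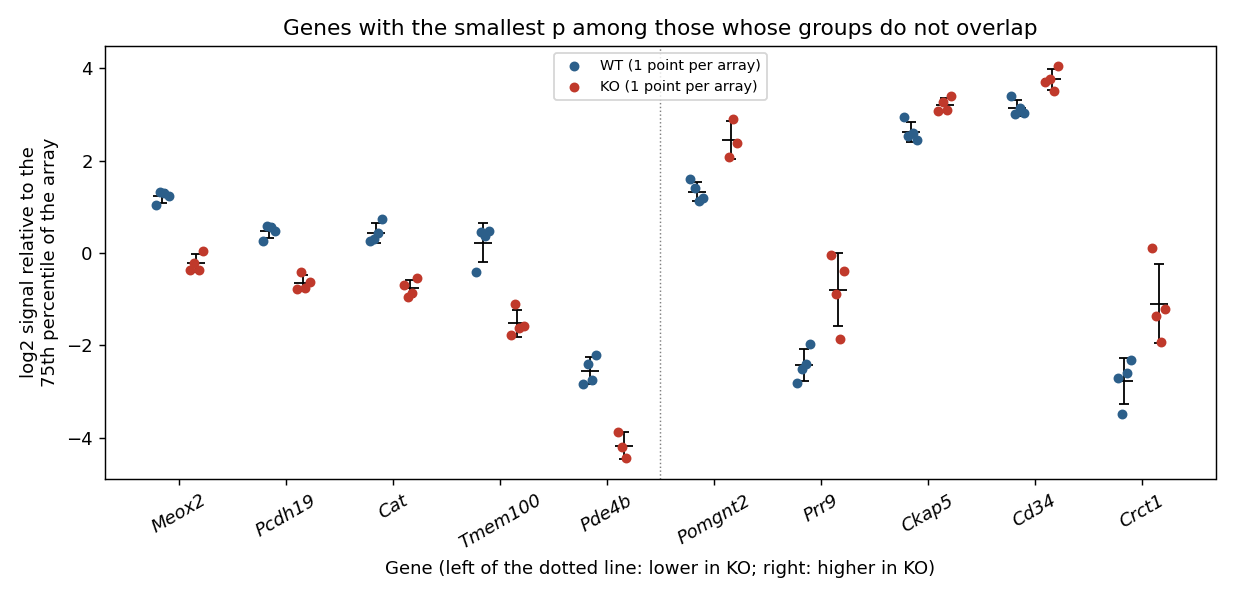
Log2 signal of 10 genes relative to the 75th percentile of each array (vertical axis) in KO and WT placentas, with 1 point per array and bars for the mean and SD. Meox2, the gene of the 10 that passed the threshold, has a mean of -0.22 in KO and 1.22 in WT.

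Gene lists are described relative to all genes, because most genes lay slightly below 0. The median log2 fold change of all genes was -0.10, and 75.6% of genes were below 0. Scaling on the median of the probes above background on all arrays moved that median to -0.0013, and moved the lower share of genes at an unadjusted p below 0.05 from 91.1% to 69.2% (215 higher, 484 lower). Of 23 lists fixed before the data were examined, camera with its preset correlation of 0.01 called 4 higher and 1 lower, and 6 had an unadjusted p below 0.05. With an estimated correlation 0 lists were called (adjusted p = 0.954 for each of the 5), and fry also called 0 lists one way or the other (lowest adjusted p = 0.116). The median and mean were below 0 while camera's direction was up for the spongiotrophoblast, giant cell, progenitor, erythroid, basement membrane, hypoxia, phagocytosis, p53, stress and sex-linked lists.

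The list of fetal endothelial genes was called lower in KO relative to all genes, without a member passing. Its genes mark endothelium in general, so the list does not separate fetal from maternal vessels. Its median log2 fold change was -0.27, or -0.17 relative to the median of all genes, and 26 of 38 measured members lay below that median (camera adjusted p = 0.0468; adjusted p = 0.954 with an estimated correlation). Robo4, a guidance receptor of endothelium, had -0.46 ± 0.12 (SE) and Ecscr, an endothelial surface protein, -0.44 ± 0.12, while Cd34 lay the other way. The list's mean was 0.91 to 1.20 on the KO arrays and 1.24 to 1.34 on the WT arrays. The list of other imprinted genes, not called by camera, also separated, at 2.52 to 2.56 in KO and 2.60 to 2.73 in WT. Relative to the mean of all genes, the endothelial list's mean differed by -0.09 (exact two-sided permutation p = 0.2). Over all genes limma called 0 members, and 0 adjusted over the list alone, with 1 higher and 9 lower at an unadjusted p below 0.05. The list lost its call without KO 3 (camera adjusted p = 0.315, median -0.08 relative to all genes), WT 1 (0.0687), WT 2 (0.0536) or WT 4 (0.193, relative median -0.10), with normexp (0.215), with the filter on all 8 arrays (0.0545), with the yolk sac list as a covariate (0.0813) and with slide column as a block (0.117).

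Lists of angiogenic signals, mesenchyme and matrix were not called by camera relative to all genes, which does not exclude a shift. The median of the mesenchyme list lay from -0.12 to -0.09 relative to all genes over the scalings. In the angiogenic signalling list (19 of 32 members below the median of all genes, camera adjusted p = 0.669) Nrp1, a VEGF co-receptor, lay at -1.08 ± 0.32 (SE) and Angpt1, a ligand of the receptor Tek, at -0.65 ± 0.23, both well above background on 2 KO and 4 WT arrays. Thbs1, an inhibitor of angiogenesis, lay at -0.51 ± 0.18. In the mesenchyme and pericyte list (22 of 31 below, camera adjusted p = 0.324) the smooth muscle genes Tagln and Myl9 lay at -0.48 ± 0.16 and -0.30 ± 0.11, and the matrix gene Postn at -0.52 ± 0.18. In the basement membrane list (18 of 32 below, camera adjusted p = 0.966) the laminin chains Lama1 and Lama2 lay at -0.76 ± 0.23 and -0.42 ± 0.22 (Lama2 -0.28 without WT 3), and Nid2 at -0.35 ± 0.16. In these 3 lists limma called 0 members over all genes and 0 adjusted over the list alone, with 4, 3 and 1 lower and 0 higher at an unadjusted p below 0.05. Without a filter on dim probes the first 2 lists were called lower (camera adjusted p = 0.022 and 0.049).

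**Figure D2:**
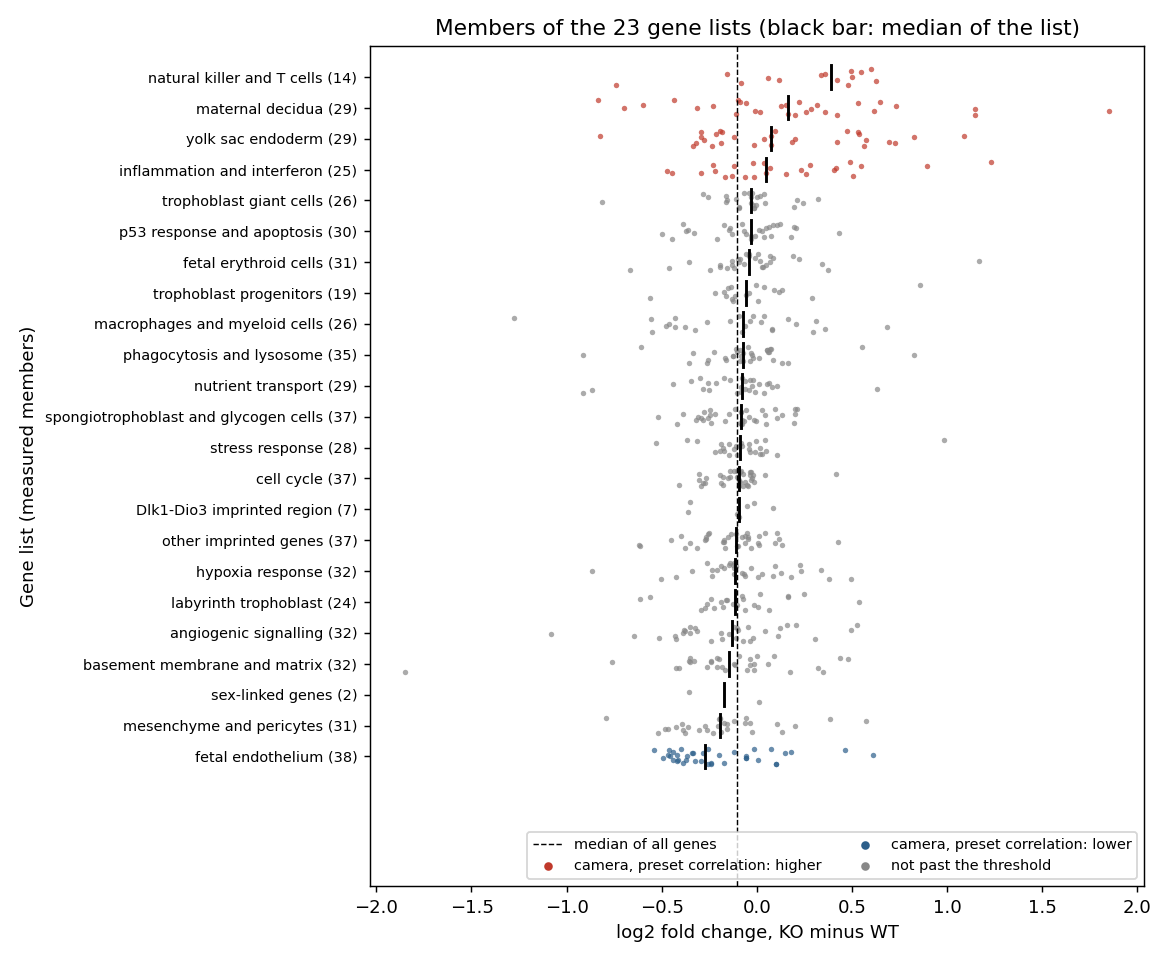
Log2 fold change, KO minus WT (horizontal axis), of the measured members of 23 lists, with 1 point per gene, a black bar at the list's median and a dashed line at the median of all genes, -0.10. Medians run from -0.27 for fetal endothelium to 0.39 for natural killer and T cells, and colours mark the lists camera called with its preset correlation.

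The lists of natural killer and T cell genes and of maternal decidua genes were called higher in KO relative to all genes, without a member passing higher. The natural killer and T cell list had a median of 0.39, or 0.49 relative to all genes, with 12 of 14 measured members above the median of all genes (camera adjusted p = 2.6e-05; adjusted p = 0.954 with an estimated correlation). The granzymes Gzmc and Gzme, proteases of uterine natural killer cells, had 0.62 ± 0.49 and 0.50 ± 0.41 (SE), Gzmf, another of them, -0.08 ± 0.53, and Itga2, an integrin subunit, 0.48 ± 0.31. Cd3e, a T cell receptor subunit, lay the other way at -0.74 ± 0.29, or -0.41 without KO 2. Gzmc lay at 0.28 without WT 1, 0.40 without KO 1 and 0.96 without WT 2, and Itga2 at 0.17 without KO 1. The decidua list had a median of 0.17, or 0.27 relative to all genes, with 22 of 29 members above (camera adjusted p = 2.2e-04; adjusted p = 0.954 with an estimated correlation). Pgr, the progesterone receptor, lay at 1.15 ± 0.32, well above background on 4 KO and 2 WT arrays. Adjusted over the list alone, limma called 2 decidua members, both lower: Igfbp4, an IGF-binding protein, at -0.70 ± 0.15 and Alpl, an alkaline phosphatase, at -0.60 ± 0.13 (adjusted p = 0.0274 each). Over all genes it called 0 members of either list, and 0 natural killer members adjusted over the list alone, with 1 higher and 3 lower decidua members and 0 higher and 1 lower natural killer member at an unadjusted p below 0.05. The natural killer call was lost without WT 1 (camera adjusted p = 0.0687), and its median relative to all genes was 0.23 without WT 1, 0.24 without KO 1 and 0.18 with array weights. The decidua call was lost with array weights (0.200), normexp (0.0506) and no filter (0.0705). The decidua median was 0.05 without KO 1, 0.07 without KO 4, 0.08 without WT 2, 0.08 without WT 4 and -0.10 with array weights, or 0.15, 0.17, 0.19, 0.19 and 0.02 relative to all genes.

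The inflammation and yolk sac lists were called higher relative to all genes, but the alternatives named below ended these calls, and the yolk sac list changed direction with the arrays used. The inflammation and interferon list had a median of 0.05, or 0.15 relative to all genes, with 17 of 25 members above (camera adjusted p = 0.00232; adjusted p = 0.954 with an estimated correlation). Its members of smallest p went both ways: Usp18 and Socs3, inhibitors of interferon and cytokine signalling, lay at -0.44 ± 0.16 and -0.47 ± 0.17 (SE), and the interferon-induced Ifit2 at 0.50 ± 0.21, or 0.32 without WT 1. The yolk sac list had a median of 0.07, or 0.18 relative to all genes, with 17 of 29 members above (camera adjusted p = 0.0468; adjusted p = 0.954 with an estimated correlation). Its transcription factors Foxa2, Gata4 and Gata6 lay at -0.30 ± 0.24, -0.32 ± 0.28 and -0.29 ± 0.29. Foxa2 ran from -0.44 without WT 3 to -0.05 without WT 1. Gata4 lay at -0.50 without KO 1 or WT 3, -0.16 without KO 3 and -0.15 without WT 4, and Gata6 at -0.45 without WT 3, -0.12 without KO 4, -0.14 without WT 1 and -0.16 without WT 2. The list's mean per array ran from -1.50 in KO 4 to 2.14 in WT 1. In both lists limma called 0 members over all genes and 0 adjusted over the list alone, with 1 higher and 2 lower in the first and 0 in the second at an unadjusted p below 0.05. The inflammation call was lost without KO 1 (camera adjusted p = 0.498, median -0.03, or 0.07 relative to all genes) or WT 1 (0.135) and with normexp (0.0506), no filter (0.168), the filter on all 8 arrays (0.312, relative median 0.03), array weights (0.370, relative median 0.08) and the decidua list as a covariate (0.0809). The relative median was 0.25 without WT 3 and 0.09 with quantile normalization. The yolk sac call was lost without KO 2 (0.450), KO 3 (0.665), WT 2 (0.562), WT 3 (0.516) or WT 4 (0.359), where the median relative to all genes was -0.08, -0.18, -0.13, 0.09 and -0.06, while it was 0.32 without KO 1, 0.60 without KO 4, 1.03 without WT 1 and 1.09 with array weights. The yolk sac call was also lost with normexp (0.167), quantile normalization (0.271), median scaling (0.688), the authors' values (0.253), no filter (0.770), the filter on all 8 arrays (0.176), slide column as a block (0.156) and the decidua list as a covariate (0.127).

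**Figure D3:**
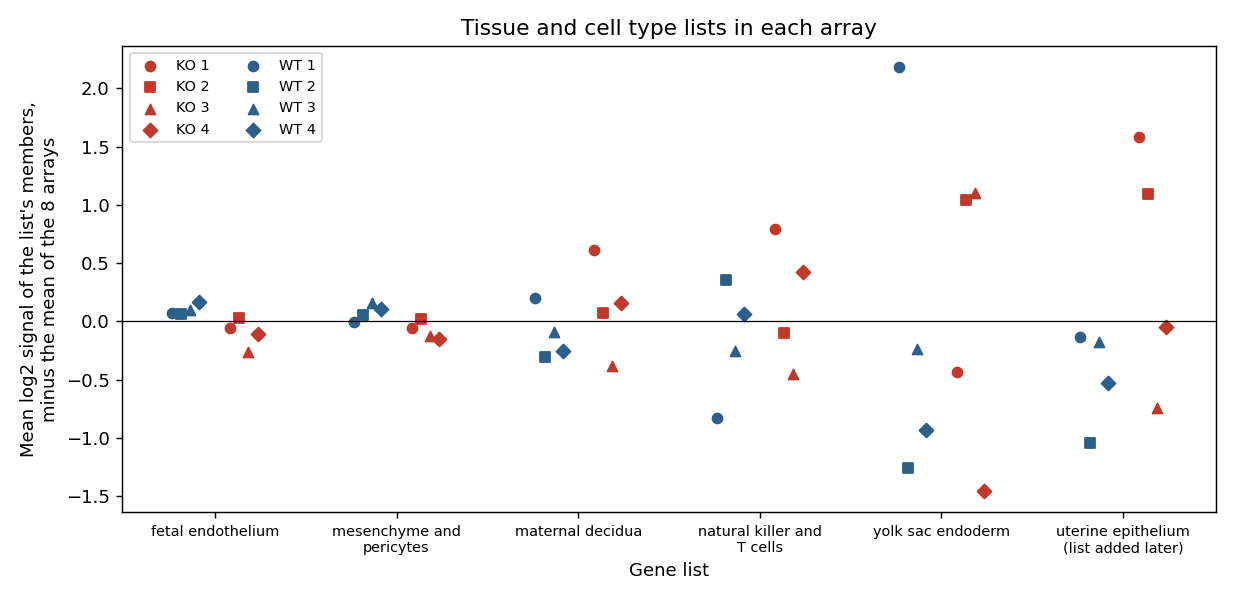
Mean log2 signal of 6 lists on each array minus the mean of the 8 arrays (vertical axis), with 1 point per array. The endothelial list is lower on the 4 KO arrays (0.91 to 1.20 before centring) than on the 4 WT arrays (1.24 to 1.34), and the yolk sac list runs from -1.50 in KO 4 to 2.14 in WT 1. Relative to the mean of all genes, not drawn here, the endothelial difference is -0.09 (exact two-sided permutation p = 0.2).

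Macrophage and erythroid lists did not pass. In the macrophage list (camera adjusted p = 0.992) Lyve1, a hyaluronan receptor of lymphatic endothelium and some macrophages, lay at -1.28 ± 0.18 (SE) and passed adjusted over the list alone (limma adjusted p = 0.00224) but not over all genes (0.189), where it passed with array weights (-1.37, limma adjusted p = 0.027). Its probe was well above background on 2 KO and 4 WT arrays. Mrc1, the mannose receptor, and Coro1a, an actin-binding protein of leukocytes, lay at -0.55 ± 0.18 and -0.46 ± 0.15. In the erythroid list (camera adjusted p = 0.0543) the water channel gene Aqp1 lay at 1.17 ± 0.89, the transcription factor gene Gata1 at 0.34 ± 0.25 and Tspo2 at -0.46 ± 0.28. Aqp1 lay at 0.33 without KO 1 and 1.79 without KO 3, Gata1 at 0.17 without KO 2 and 0.22 without WT 3, and Tspo2 at -0.22 without WT 4. Over all genes limma called 0 members of either list, and 0 erythroid members adjusted over the list alone, with 0 higher and 4 lower macrophage members and 0 erythroid members at an unadjusted p below 0.05. The erythroid list was called higher without KO 3 (camera adjusted p = 0.00326), KO 4 (0.0499) or WT 1 (0.00135), with quantile normalization (0.0415) and with the authors' values (0.0409).

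Slc2a1, the glucose carrier GLUT1, was lower in KO within its lists. It lay at 5.03 ± 0.37 in KO and 5.89 ± 0.17 in WT (SD, n = 4 each), without overlap, and passed adjusted over the list alone for nutrient transport (limma adjusted p = 0.0491) and hypoxia (0.0271) but not over all genes (0.439), where it passed with array weights (-1.02, limma adjusted p = 0.0496). Pdk1, a kinase that restrains pyruvate oxidation, had a log2 fold change of -0.50 ± 0.10 (SE) and passed adjusted over the hypoxia list alone (limma adjusted p = 0.0271). Of other members, the phosphofructokinase gene Pfkp lay at -0.24 ± 0.10, the fatty acid receptor gene Cd36 at -0.91 ± 0.28 and the fatty acid transporter gene Slc27a4 at -0.44 ± 0.21, or -0.28 without KO 3. Neither list was called by camera (adjusted p = 0.858 for transport and 0.809 for hypoxia), and limma called 0 members over all genes, with 0 higher and 2 lower transport members and 1 higher and 3 lower hypoxia members at an unadjusted p below 0.05. The mixed test of fry, which asks for change in either direction, did call the hypoxia list (adjusted p = 0.0049).

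Trophoblast lists did not pass. In the labyrinth list (camera adjusted p = 0.963) Tead4, a transcription factor of trophectoderm, lay at -0.56 ± 0.15 (SE), its cofactor Vgll1 at -0.61 ± 0.22 with -0.19 from a dimmer probe, and the gap junction gene Gjb2 at -0.23 ± 0.11. In the spongiotrophoblast list (camera adjusted p = 0.220) Prl6a1, Prl8a6 and Car2 lay at 0.20 ± 0.12, -0.52 ± 0.32 and 0.20 ± 0.14, with Prl8a6 at -0.81 without WT 1 and -0.31 without WT 3, and Car2 at 0.13 without KO 1. In the giant cell list (camera adjusted p = 0.218) Prl2c5 lay at -0.81 ± 0.33 with -0.02 from its other probe, Serpinb9e at -0.26 ± 0.16 and Prl5a1 at 0.32 ± 0.22. Without WT 4 these 3 lay at -0.51, -0.11 and 0.55, and with normexp Prl2c5 lay at 0.06. In the progenitor list (camera adjusted p = 0.669), which also holds Tead4, Pcsk6 and Esrrb lay at 0.86 ± 0.53 and 0.29 ± 0.19, with Pcsk6 at 0.36 without WT 4 and 0.50 without KO 1, and Esrrb at 0.19 without WT 3 and 0.45 without WT 1. In these 4 lists limma called 0 members over all genes and 0 adjusted over the list alone, with 2, 0, 1 and 1 lower and 0 higher at an unadjusted p below 0.05. The spongiotrophoblast list was called higher without KO 2 (camera adjusted p = 0.0184), KO 4 (0.0379) or WT 4 (0.0096) and with the decidua list as a covariate (0.0236), and the giant cell list without KO 2 (0.0262) or WT 4 (0.00186).

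Cell cycle, apoptosis, stress and phagocytosis lists did not pass. Of cell cycle genes (camera adjusted p = 0.858) Mcm2 and Pcna, of DNA replication, lay at -0.41 ± 0.17 and -0.27 ± 0.12 (SE), and Rrm2, a ribonucleotide reductase subunit, at 0.42 ± 0.21. Pcna lay at -0.17 without WT 1 and Rrm2 at 0.22 without KO 1. In the p53 and apoptosis list (camera adjusted p = 0.669) Bid, Casp8 and Cycs lay at -0.37 ± 0.13, -0.44 ± 0.19 and -0.36 ± 0.14, with -0.01 from another Cycs probe. In the stress list (camera adjusted p = 0.669) Nqo1, Chac1 and Atf3 lay at -0.53 ± 0.21, 0.98 ± 0.68 and -0.19 ± 0.12, with Chac1 at 0.38 without KO 1 and 1.66 without KO 3. In the phagocytosis list (camera adjusted p = 0.345), which also holds Cd36, Gas6, a ligand of receptors that clear dying cells, lay at -0.33 ± 0.11 and Gpnmb at 0.83 ± 0.41, or 0.49 without KO 1. In these 4 lists limma called 0 members over all genes and 0 adjusted over the list alone, with 1, 3, 1 and 2 lower and 0 higher at an unadjusted p below 0.05. Without KO 1 the cell cycle list was called higher (camera adjusted p = 0.0333).

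Genes of the Dlk1-Dio3 list did not pass. Its members Wdr25 and Ppp2r5c, at 110266322 and 111820692 of chromosome 12 (mm9), flank the stretch of probes given below. Whether they are imprinted was not examined. Dlk1, a paternally expressed Notch-like ligand, had a log2 fold change of -0.36 ± 0.17 (SE, limma adjusted p = 0.804), with -0.56 from a dimmer probe, and Meg3, a maternally expressed long noncoding RNA, -0.35 ± 0.16 (limma adjusted p = 0.804). Without WT 4 Meg3 lay at -0.20. Mirg lay at 0.08 ± 0.22, from -0.03 without KO 4 to 0.29 without WT 4, and Ppp2r5c at -0.10 ± 0.14, from -0.22 without WT 4 to -0.04 without WT 1. Dio3, Dio3os and Wdr25 lay at -0.10 ± 0.14, -0.05 ± 0.21 and -0.02 ± 0.19, and at 0.0056, 0.05 and 0.09 with median scaling. Leaving out 1 array gave -0.18 (KO 3) to -0.0018 (KO 1) for Dio3, -0.23 (WT 1) to 0.06 (WT 4) for Dio3os and -0.17 (KO 1) to 0.08 (WT 4) for Wdr25. The Dlk1-Dio3 list was not called (camera adjusted p = 0.858), and limma called 0 of its 7 measured members over all genes and 0 adjusted over the list alone, with 0 at an unadjusted p below 0.05. Between 110270408 and 111518851 of chromosome 12 (mm9), 37 of 123 probes were detected, and limma called 0 of them (lowest adjusted p = 0.647), with 0 higher and 2 lower at an unadjusted p below 0.05. The 2, chosen after their values were seen, belonged to Meg3 (-0.33 ± 0.13 SE) and to 6430411K18Rik (-0.54 ± 0.17), an RNA at 110830889 to 110830948 that the gene table also lists as an antisense transcript of Peg11.

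**Figure D4:**
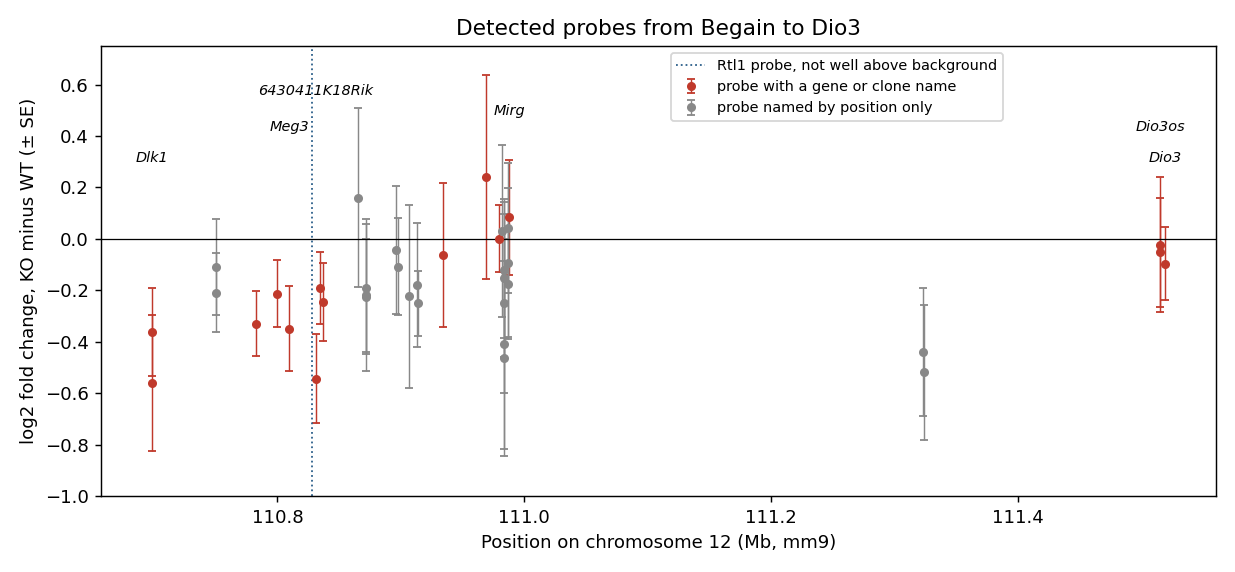
Log2 fold change, KO minus WT, with SE (vertical axis) of the 37 detected probes by position on chromosome 12 in Mb, mm9 (horizontal axis), with a dotted line at the Rtl1 probe, which was not well above background. Values run from -0.56 at Dlk1 to 0.24, and 0 of the probes passed the threshold, with 2 lower at an unadjusted limma p below 0.05.

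Imprinted genes elsewhere were not called as a list (20 of 37 members below the median of all genes, camera adjusted p = 0.504). The paternally expressed neighbours Magel2 and Ndn lay at -0.62 ± 0.20 and -0.61 ± 0.21 (SE), and Nap1l4 at -0.45 ± 0.15, with -0.02 from a dimmer probe and 0.36 with the mean of its probes. Over all genes limma called 0 members, and 0 adjusted over the list alone, with 0 higher and 5 lower at an unadjusted p below 0.05. Without a filter on dim probes the list was called lower (camera adjusted p = 0.0028). The sex-linked list, with 2 measured members, was not called (camera adjusted p = 0.992). Ddx3y lay at 0.01 ± 0.15, and at -0.12 with array weights, and Eif2s3y at -0.36 ± 0.27. Leaving out 1 array gave -0.11 (WT 1) to 0.10 (WT 3) for Ddx3y, and for Eif2s3y -0.56 (KO 1), -0.57 (WT 2) and -0.24 (KO 3). In this list limma called 0 members over all genes, 0 adjusted over the list alone and 0 at an unadjusted p below 0.05.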

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

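The splits for genes past the threshold, the 3 tests of Meox2 and the test of the decidua and natural killer lists were chosen only after the result was seen. In 13 of 205 groups of 4 arrays, 1 array stood apart from the other 3 (gap to the nearest over the range, above Dixon's 95% critical value), and chance gives about 1 in 20 groups, or 10.2 here. WT 4 was apart in 4 of the 13.

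Among the KO arrays, Casp8 was highest in KO 2 (-0.23, next -0.68; ratio 0.9248), Foxa2 in KO 1 (0.34, next 0.12; 0.8373), Gas6 in KO 4 (-0.04, next -0.25; 0.9041) and Tead4 in KO 1 (1.58, next 1.09; 0.9035). Among the WT arrays, WT 4 was highest for Meg3 (5.80, next 5.27; ratio 0.8457), Mirg (4.14, next 3.34; 0.9671) and Serpinb9e (7.73, next 7.16; 0.9363) and lowest for Pcsk6 (0.34, next 2.28; 0.9366). Gpnmb was highest in WT 2 (0.25, next -0.36, ratio 0.8757), Tead4 highest in WT 3 (1.99, next 1.71, ratio 0.8363) and Tmem100 lowest in WT 1 (-0.41, next 0.36, ratio 0.8695). The mean of the macrophage list was highest in WT 3 (-0.44, next -0.55, ratio 0.8747), and that of the spongiotrophoblast list lowest in WT 1 (3.31, next 4.06, ratio 0.8868).

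Meox2 passed the threshold in the real grouping. Of 35 splits of the 8 arrays, 1, the real one, gave as many genes (1 against at most 0 in the others), a share under 0.05. This is the smallest share that 35 splits can give. The adjusted threshold seldom lets a gene pass in any split, so the comparison, chosen after the call, adds little to the adjusted p. Chance is not excluded. The count rests on 1 gene: it was 0 in 7 of 8 fits without 1 array (limma adjusted p of Meox2 from 0.0516 without WT 1 to 0.338 without WT 2) and with the slide column as a block (0.133), and 8 of 35 splits gave as many genes at an unadjusted p below 0.05. Scaling is argued against as the whole cause of the fold change, since the value closest to 0 over 4 other scalings was -1.267. Median scaling moved the median of all genes only from -0.10 to -0.0013, so it could hardly have removed such a change. The call itself did depend on scaling. It was lost with normexp (limma adjusted p = 0.0678) and median scaling (0.141). An even loss of all endothelial cells alone is likewise argued against, since the endothelial list had a median of -0.2722 with a lower quartile of -0.4086. Loss of a subset of vascular cells, such as those of the fetal capillaries alone, stays open. The list does not separate subsets, or fetal from maternal vessels. The slide row stays open, because 0 slide rows hold both groups, and so does the genotype itself.

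The decidua and natural killer lists were among 5 called, but 19 of 35 splits called as many lists, up to 14, so chance is not excluded. More maternal tissue in the KO samples could raise both lists, but whether it did stays open: array deviations from the group means of the 2 lists had a Pearson r of 0.2873 (permutation p = 0.575) and a Spearman rho of 0.190 (permutation p = 0.705) over 8 arrays, and r was -0.84 without KO 1 and KO 3. Adjusted over these 2 coefficients, both p values are 0.705.

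More genes were lower than higher in KO at an unadjusted p below 0.05, 91.1%. In 2 of 35 splits the share going one way was as large (91.8% in the other), so chance is not excluded, and 8 splits gave as many genes at that p, up to 2614 against 1129. Scaling on the median gave 69.24% lower, between the shares set for and against scaling as the cause, so that explanation is undecided. A biological cause was not tested apart from the grouping.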

How the results depend on the processing

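The yolk sac list as a covariate and the exact permutation of list means were chosen only after the result was seen. Over all alternatives 488 list results and 1509 named gene results kept direction and side of the threshold, 54 counts stayed within 1.5 times, and Rtl1 gave no value because its probe was not well above background. The cause of a change was not tested unless stated, and dim probes, with signal near background, limit what the arrays can show.

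Normexp gave 0 genes lower, 1 list higher and 0 lower, with Meox2 at -1.27, Dio3os at 0.039, Prl2c5 at 0.059 and Wdr25 at 0.058 (the last 3 with changed sign), and adjusted p of 0.215 for endothelium, 0.0506 for decidua, 0.167 for yolk sac and 0.0506 for inflammation. Quantile normalization and the authors' table each gave 2 genes lower, Meox2 and an unnamed probe, with yolk sac at 0.271 and 0.253. Median scaling gave 0 genes lower, Meox2 at -1.35, yolk sac at 0.688, and Dio3, Dio3os and Wdr25 with changed sign at 0.0056, 0.049 and 0.087. No filter gave 0 genes lower, Meox2 at -1.45 (limma adjusted p = 0.674, with 36065 genes tested), 1 list higher and 4 lower, decidua at 0.0705, yolk sac at 0.770 and inflammation at 0.168. The filter on all 8 arrays gave 2 lists higher and 0 lower, with endothelium at 0.0545, yolk sac at 0.176 and inflammation at 0.312. With the mean of probes Nap1l4 changed sign to 0.36, by construction: its dimmer probe, far below the other, has a missing value in KO 1, which lifts that array's mean. Array weights (WT 3 4.58, KO 3 2.29, KO 1 0.47, WT 4 0.38) gave 3 genes higher and 50 lower, 2 lists higher, decidua at 0.200, inflammation at 0.370 and Ddx3y at -0.12, with changed sign. The decidua covariate gave 0 genes lower, 2 lists higher, Meox2 at -1.42, yolk sac at 0.127, inflammation at 0.0809 and Dio3os at 0.094, with changed sign. The yolk sac covariate gave 0 lists lower, with endothelium at 0.0813.

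With slide column as a replicate block, 0 genes and 0 lists were lower, with Meox2 at -1.45 (limma adjusted p = 0.133), endothelium at 0.117 and yolk sac at 0.156. Same-numbered arrays correlated at 0.17, 0.32, 0.09 and 0.29 in their deviations, so 1 lies under 0.1 and the numbers were not taken as a pairing. Every sample correlated best with its own number, a hint from the data and not the design. The 75th percentile of the processed signal was also highest in KO 2 and WT 2 (1453 and 1490) and lowest in KO 4 and WT 4 (743 and 629). An effect of the slide column is therefore not excluded, and the main fit leaves it out.

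An estimated correlation gave 0 lists higher and 0 lower (0.954 for all 5). Fry gave 0 and 0, with 0.116 for endothelium, 0.813 for decidua, 0.614 for natural killer cells, 0.873 for inflammation and 0.976 for yolk sac, the last with its direction reversed. The exact permutation of list means gave 0 and 0, with 0.889 for 4 of the lists and 1 for yolk sac. The smallest p this permutation can give with 4 against 4 arrays is 0.0286. After adjustment over the lists, none could pass unless many of them reached that value together. The permutation could therefore hardly have called a list, and its 0 calls do not count against the calls by camera.

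Leaving out 1 array gave 0 to 1 genes lower, 3 to 6 lists higher and 0 to 1 lower, with Meox2 from -1.54 to -1.40. Camera's adjusted p ran from 0.00579 to 0.315 for endothelium, 4.0e-08 to 0.0333 for decidua, 4.0e-09 to 0.0687 for natural killer cells, 1.3e-08 to 0.665 for yolk sac and 3.1e-05 to 0.498 for inflammation. The cell cycle list, 0.0333 to 0.868, turned higher without KO 1. Values that changed sign ran from -0.23 to 0.057 for Dio3os, -0.17 to 0.078 for Wdr25, -0.11 to 0.10 for Ddx3y and -0.034 to 0.29 for Mirg.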

Other observations

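The uterine epithelium list and the genes named here were chosen only after the result was seen. Some genes differed between arrays far more than between groups. The yolk sac list spanned 12.5-fold between arrays, with Afp, the fetal serum protein of yolk sac endoderm, from -0.41 in KO 4 to 6.92 in WT 1 (161-fold) and Ttr, a thyroid hormone carrier, spanning 54.9-fold. Afp averaged 3.52 ± 2.89 in KO and 2.96 ± 2.84 in WT (SD, n = 4 each). Rn18s, ribosomal RNA, spanned 317-fold, from -2.53 in KO 2 to 5.78 in KO 4.

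Genes of uterine and barrier epithelium were high on some KO arrays. A list of 23 such genes, 20 of them measured, had a mean of -1.17 ± 1.06 in KO and -2.11 ± 0.42 in WT (SD, n = 4 each, exact two-sided permutation p = 0.2), highest in KO 1 (-0.06) and KO 2 (-0.55). Foxa2, Lcn2, C3 and Spink1 of this list also stand in other lists. Among its members Sprr2a2 lay at 5.90 ± 0.50 in KO and 5.07 ± 0.61 in WT, and Padi2 at 3.19 ± 0.98 and 2.42 ± 0.47 (SD, n = 4 each). KO 1 held Prap1 at 3.75, Sprr2h at 2.98 and Sprr2d at 2.11, against 3.10, 1.28 and -0.79 in KO 2. Sprr2d and Sprr2h, small proline-rich proteins of epithelial barriers, had log2 fold changes of 3.09 ± 0.85 and 3.35 ± 0.94 (SE) without overlap of the groups but did not pass (limma adjusted p = 0.484 and 0.501). They were well above background on 4 KO and 2 WT arrays, and lie on chromosome 3 (mm9) from 92144721 and 92191160, between Prr9 (91926126) and Crct1 (92818192).

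On KO 4, 20 spots without an outlier flag lay more than 4 log2 units below the same spot on every other array, in columns 151 to 159 of 164 and rows 8 to 134 of 384. They touch 17 genes, among them Itga5, at -5.14 in KO 4 and 0.53 to 1.85 elsewhere, and its KO mean is therefore not given as a difference, although it stays among the members of the matrix list. Spots more than 4 log2 units above every other array numbered 140, 79, 254 and 276 on KO 1 to KO 4. On WT 1 to WT 4 they numbered 16, 46, 13 and 19. Those without an outlier flag numbered 46, 8, 8 and 9 on the KO arrays and 5, 5, 2 and 3 on the WT arrays. Their effect on the lists was not tested.

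A hypothesis written before its test was that changed genes lie near the targeted locus, as flanking DNA of another strain could produce. Within 20 Mb of the Rtl1 probe 6 of 192 genes had an unadjusted p below 0.01, against 296 of all 17396 genes with a position (Fisher's exact test, two-sided, odds ratio 1.881, 95% interval 0.676 to 4.22, p = 0.147), which leaves the question open. On the whole of chromosome 12 the count was 16 of 640.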
